A study of Mus musculus with 6 samples.

How the data were processed

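The series holds 6 Illumina bead arrays of mouse cancer-associated fibroblasts, 3 from plates treated with 2 micromolar DAC for 48 hours and 3 from untreated plates. Per the labels, total RNA was taken with Trizol and biotin-labelled cRNA was made with an Ambion kit. The scanner software, its version and the genome build behind the probe annotation are not given in the sources used here. The deposited table gave, for each of 45281 probes and each array, a mean bead intensity on a linear scale, neither normalized nor background-subtracted as judged from its positive and unequal values. Per the file headers it also gave a detection p-value, the standard error of the bead intensity and the number of beads per probe. The median number of beads was 43 to 44 per array and the fewest 10. The steps of the detection p-values implied 936 negative control probes. Columns were assigned to samples by the sample names in the labels.

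A further deposited table of intensity values listed probes under identifiers of which 0 were shared with the first table, so its probes stayed unnamed. Its scale was linear, and it was background-subtracted and quantile normalized as judged from the values, not from a statement of the authors. The median of each of its 6 columns was 4.3 and 33.4% of its values were below 0. Of 1687 probes among the 2000 brightest on every array in both tables, 1468 had the same 6 ranks, and at most 15 did with the columns in another order. It served only for counts of probes.

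Background was corrected by normexp with parameters inferred from the detection p-values (limma 3.58.1 in R 4.3.3), an offset of 16 was added, and the arrays were quantile normalized on the log2 scale. Probes with a detection p under 0.01 on at least 3 arrays were kept, 16883 in all. Each gene was represented by its brightest kept probe, which gave 11518 genes, 9968 of them with a symbol of the reference. Of 3761 genes with more than 1 kept probe, 26 had probes past the threshold in opposite directions. Probe names were updated through a table of gene names of the mouse assembly GRCm38.p6, used for names alone. By symbol, 27760 probes matched, 7994 by synonym and 920 by gene identifier, together 36674 (81.0%). Names that matched several genes (187 probes), date-like names (40) and unmatched names (8380) were kept as in the table. A probe reads 1 part of a transcript, and probes of near-identical genes can read each other's transcripts.

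DAC and untreated arrays were compared with limma's lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. A gene counted as detected only with DAC where a probe had a detection p under 0.01 on all 3 DAC arrays and over 0.05 on all 3 untreated arrays, and the opposite likewise. For a probe below detection on every array of a group, the fold is a bound. The mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the lowest detected signal on that array or the probe's own signal, whichever was higher. Gene lists and cell type markers, 26 in all, were written before the data were examined, and the 24 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 (two-sided), again with an estimated correlation, and with fry. The p-values of each kind were adjusted over the 24 lists. Counts per list are given over all genes tested and adjusted over the list alone.

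The named genes follow a rule fixed before the data were examined. They are Dnmt1, Dnmt3a, Dnmt3b and Uhrf1, the 12 largest rises and 12 largest falls among called genes detected on all 6 arrays without overlap between the groups, the 10 genes with the smallest p among those detected only with DAC and 10 among those detected only without it, and up to 4 called members of each list with the smallest p. Predicted and clone names were passed over, as were date-like names and names shared by several genes, and some genes that the rule takes are not reported here. Of 51 genes at least 4-fold higher, 12 had such names or none. List members named because they missed the threshold or were not detected were chosen after their values were seen.

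The pipeline was tested on simulated intensities with levels and spread taken from the real arrays and noise drawn independently for each probe. Of 50 genes changed by each size, 46% were called at a log2 change of 0.5, 96% at 1, 96% at 2 and 100% at 3. Of 180 genes called among 14342 tested, 6.1% had not been changed. Only 200 genes were changed there, while 3394 of the 11518 real genes were called. The adjusted threshold was thus stricter in the simulation, and the shares called there do not carry over directly to the real arrays. With no changes, 0 of 14569 genes were called, and over 20 such simulations 1 of 498 list tests was called with the preset correlation and 0 with an estimated one. Since the simulated probes varied independently, these list counts do not cover lists whose genes vary together. More genes passed the detection filter in the simulations than the 11518 of the real arrays. The median residual SD of the real genes was 0.127 on the log2 scale.

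The alternatives tried were no background correction, an offset of 50, scaling to the 75th percentile, cyclic loess, no between-array normalization, the further deposited table, no filter and 2 other filters on dim probes, the mean of a gene's probes, an intensity-trended and robust variance model, array weights, the replicate number as a block, other detection thresholds and leaving out each array in turn. Data preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.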

Results

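The series measured gene expression with Illumina bead arrays in cancer-associated fibroblasts, the stromal fibroblasts that surround a carcinoma. The cells were grown for a short time as an explant from one pancreatic tumour of a KPC-Brca1 mouse, a mouse model of pancreatic cancer. Of the 6 plates, 3 received 2 micromolar decitabine (5-aza-2'-deoxycytidine, here DAC) for 48 hours and 3 stayed untreated. DAC is a cytidine analogue that is built into DNA and traps DNA methyltransferases there. The title of the series asks which genes the drug activates in these cells. Each array held 45281 probes, of which 16254 to 17180 were detected on the untreated arrays and 16205 to 16528 on the DAC arrays (detection p under 0.01). The 75th percentile of the raw intensity was 114.0 ± 3.0 (SD, n = 3) on the untreated arrays and 102.1 ± 4.9 on the DAC arrays. Across probes, the arrays of one group correlated at 0.996 to 0.997 and arrays of different groups at 0.988 to 0.990. On the first principal component, which carried 74.9% of the variance, the untreated arrays lay between −24.1 and −20.4 and the DAC arrays between 22 and 22.6. The plates were replicates of one explant culture, so p-values measure only the spread between plates, and their number limits the precision.

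DAC changed the expression of 3394 of 11518 genes tested. At an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1708 genes were higher and 1686 lower with DAC. At least 2-fold differences were found for 231 genes that were higher and 99 that were lower, at least 4-fold differences for 51 and 2 genes, and 11 genes were at least 8-fold higher. Among genes detected on all 6 arrays, the largest rise belonged to Psg23, a pregnancy-specific glycoprotein, whose log2 intensity went from 5.92 ± 0.05 to 11.24 ± 0.20 (SD, n = 3 per group), a 39.7-fold difference (adjusted p = 9.41e-14). The water channel gene Aqp1 rose 8.25-fold, Glipr1 6.75-fold and Gstp2, a glutathione S-transferase, 5.78-fold. Over the alternatives, the log2 change of Psg23 (5.31) ran from 4.69 to 5.42 and that of Gstp2 (2.53) from 1.93 to 2.59. Passing over targets with a predicted, clone or ambiguous name, some of which rose as much, the other 8 of the 12 genes with the largest rises were Usp18, Apol9b, Ifit3b, Ifit3, Apol9a, Isg15, Gbp3 and Oas1g, at 5.12-fold to 6.81-fold. Near-identical family members (Psg23, Gstp2, Apol9a with Apol9b, Ifit3 with Ifit3b, the Oas genes) can share a probe's signal, so the copy that changed is uncertain.

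The largest fall among genes detected on all 6 arrays was that of Igfbp3, which encodes a binding protein of insulin-like growth factors, from 10.91 ± 0.23 to 8.76 ± 0.13 on the log2 scale, 4.45-fold lower (adjusted p = 7.58e-09). The alarmin cytokine gene Il33 was 3.54-fold lower, Selp (P-selectin) 3.44-fold, Cxadr (the coxsackievirus and adenovirus receptor) 3.15-fold and Bmp4 2.98-fold. Gpc3, Lpl (lipoprotein lipase), Trf (transferrin), Ptprd and Fads2 (a fatty acid desaturase) were 2.84-fold to 2.91-fold lower. Hmox1, the heme oxygenase gene, was 2.9-fold lower on average, but its DAC plates differed widely (7.76, 6.56 and 8.80 against 9.24 ± 0.18 untreated). Its log2 change was −1.54 with all plates and −0.96 without DAC replicate 2. The call (adjusted p = 0.00465) ended without the filter on dim probes (adjusted p = 0.14) and with an intensity-trended, robust variance model (adjusted p = 0.15), the highest of a range that began at 3.64e-05 over 18 alternatives.

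Without between-array normalization, the split of the calls was 977 higher and 2711 lower, so 26.5% of called genes were higher in place of 50.3%. The median change of all genes then lay at −0.111 (log2), against 0.003 after quantile normalization. The counts of at least 2-fold changes also moved with other settings. They were 128 higher and 49 lower with an offset of 50 in place of 16, 64 lower without background correction, and 188 higher and 171 lower without between-array normalization.

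Most germline genes that could be measured rose with DAC. Of 21 tested members of the germline and meiosis list, 19 rose and none fell. Counts adjusted over the list alone were 19 and 1. The list's median log2 change was 1.27 (limma camera adjusted p = 2.98e-19; adjusted p = 0.00639 with an estimated correlation). With the 11 members that lay below detection in one group set to their bound, the median was 1.01. Such members passed the detection filter because they were detected on the arrays of the other group, and without the filter the median was 0.05 (camera adjusted p = 6.92e-09). It was 0.82 with an offset of 50, which shrinks the changes of dim probes. Rhox5, a homeobox gene of the reproductive cluster on the X chromosome, was not detected on any untreated array and was at least 23.5-fold higher with DAC (log2 intensity 4.76 ± 0.05 against 9.49 ± 0.13, SD, n = 3; adjusted p = 9.41e-14). Tex19.1, a testis-expressed gene, was at least 7.63-fold higher, Taf7l, a transcription factor subunit of male germ cells, at least 6.62-fold, and Dazl, a germ cell RNA-binding protein, at least 4.65-fold. Of 76 germline genes on the array, 55 did not pass the detection filter. These included the meiotic genes Sycp1, Sycp3 and Dmc1, detected on 0 of 6 arrays. A probe at background does not show that its transcript was absent, since the probes of Pcna and Hspa5, genes that most growing cells express, lay at background on all 6 arrays too.

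Across all genes, 63 had a probe detected on all 3 DAC arrays and on no untreated array (detection p over 0.05), and 38 showed the opposite. Counting a gene as off only where all of its probes were, these numbers were 53 and 23. Among the named genes of the first kind, Slc47a1, a membrane transporter of organic cations, had the smallest p-value and was at least 12.4-fold higher with DAC. Its fitted log2 change was 4.24 for the brightest probe and 2.31 for the mean of its probes. Got1l1 was at least 5.09-fold higher, Ltc4s (a leukotriene synthase) at least 4.54-fold, Rhox2e at least 4.00-fold, Pkd1l2 at least 3.56-fold, Gpat2 at least 2.91-fold, Cyp2c55 at least 2.66-fold and the prolactin gene Prl at least 2.47-fold. In the opposite direction, Unc13c was at least 2.33-fold lower with DAC, Nell2 at least 1.69-fold, Pcp4l1 at least 1.68-fold, Ppp2r2b at least 1.66-fold and Agmat at least 1.56-fold. Amer2, Prr15l, Col24a1, Pdzd7 and Epha7 were at least 1.13-fold to 1.4-fold lower. Both counts depended on the detection threshold. They were 156 and 166 at a detection p of 0.05 for both sides, and 25 and 0 with detection under 0.001 against over 0.1. The count of genes detected only without DAC was 80 without untreated replicate 1 and 62 without DAC replicate 1. Leaving out an array can raise such a count but not lower it, since fewer arrays must meet the thresholds.

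**Figure D1:**
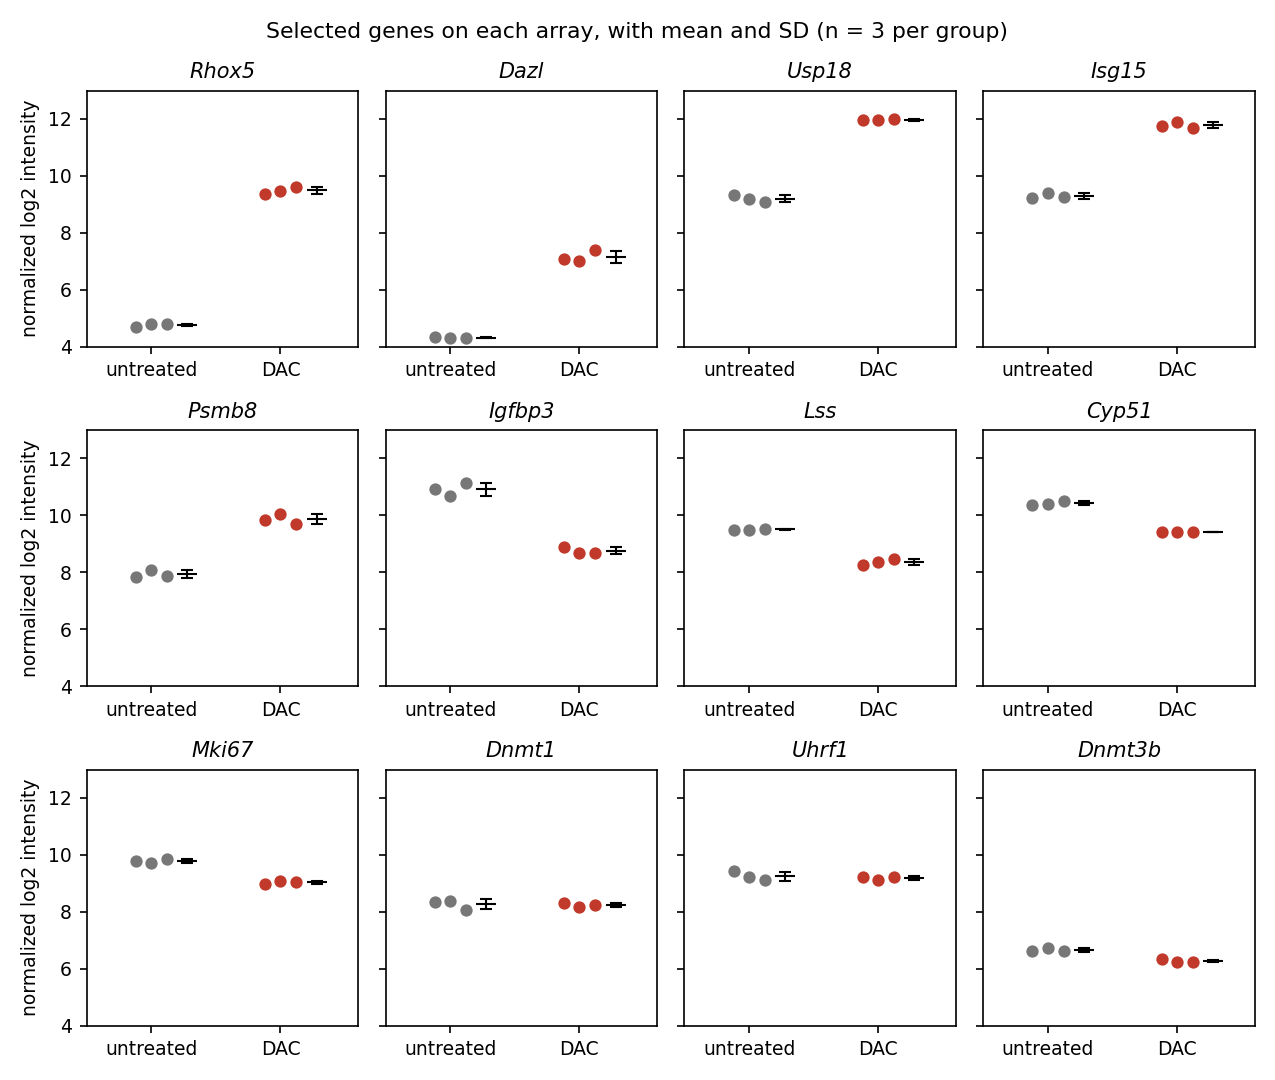
Normalized log2 intensity of 12 genes on each array (points: untreated in grey, DAC in red; n = 3 per group), with the mean and SD beside them. The DAC points lie above the untreated points for Rhox5, Dazl, Usp18, Isg15 and Psmb8, below them for Igfbp3, Lss, Cyp51, Mki67 and Dnmt3b, and among them for Dnmt1 and Uhrf1.

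Almost all interferon-stimulated genes that passed the detection filter rose. Of 59 tested members, 55 were higher and none was lower with DAC (57 and 0 adjusted over the list alone). The array held 90 members, and those not tested included Ifit1, Mx1 and Ifih1, detected on no array. Their median log2 change was 1.21 (camera adjusted p = 3.99e-44; adjusted p = 0.00268 with an estimated correlation). Usp18, which removes the ubiquitin-like protein ISG15 from its targets, rose from 9.20 ± 0.12 to 11.97 ± 0.03 (6.81-fold, adjusted p = 5.93e-11). Oas2, an antiviral oligoadenylate synthetase detected on 1 of 3 untreated arrays, rose with a fitted log2 change of 2.70 (1.83 to 2.77 over the alternatives), Ifit3 rose 5.96-fold and Apol9a 5.66-fold. The members that did not pass the test were Apobec3, Ifi27, Ifit2 and Zbp1, with log2 changes of 0.02 to 0.31.

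Genes of antigen presentation rose as well, 18 of 22 tested, with no member lower (18 and 0 adjusted over the list alone). The array held 35 members, and those not tested included Nlrc5, Ciita and H2-Aa, detected on no array. The median log2 change was 0.75 (camera adjusted p = 4.53e-10; adjusted p = 0.0113 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, rose 3.82-fold, from 7.93 ± 0.14 to 9.87 ± 0.18. The immunoproteasome subunits Psmb9 and Psmb10 rose 2.57-fold and 2.37-fold, and the non-classical class I gene H2-T23 2.51-fold.

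Among chemokines and cytokines, 15 of 27 tested genes rose and 4 fell (17 and 4 adjusted over the list alone). The median log2 change was 0.50, or 0.31 with the 4 members below detection in one group at their bound. It was 0.31, 0.24 and 0.32 without DAC replicate 1, 2 and 3. The list passed the test with the preset correlation (camera adjusted p = 0.000166) and did not with an estimated correlation (adjusted p = 0.0871). Cxcl10, a chemokine that attracts T cells, rose 2.69-fold, Il15 2.37-fold, and Ccl4 was at least 1.88-fold higher. Il33 moved the other way.

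Leukocyte markers were higher with DAC beside these groups. Of 13 tested markers of macrophages and other leukocytes, 10 rose and none fell (10 and 0 adjusted over the list alone), with a median log2 change of 0.63, or 0.56 with 2 members at their bound and 0.33 with an offset of 50. This list passed with the preset correlation (camera adjusted p = 7.36e-06) and not with an estimated one (adjusted p = 0.0730). Cd53 was at least 2.00-fold higher, Laptm5 2.29-fold, Lyz1, a lysozyme gene, 1.72-fold, and Csf1r, the receptor of macrophage colony-stimulating factor, at least 1.33-fold. Of 33 such markers on the array, 20 were detected on no array, among them the pan-leukocyte gene Ptprc.

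Cholesterol synthesis genes fell together. Of 22 tested members, 20 fell and none rose (20 and 0 adjusted over the list alone). The median log2 change was −0.88 (camera adjusted p = 9.79e-16; adjusted p = 0.00792 with an estimated correlation). Lss (lanosterol synthase) went from 9.51 ± 0.02 to 8.37 ± 0.11 and was 2.2-fold lower (adjusted p = 6.94e-07), Acat2 2.15-fold and Cyp51 (lanosterol demethylase) 2.04-fold.

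Cell cycle genes also fell. Of 53 tested members, 33 were lower and none was higher with DAC (35 and 0 adjusted over the list alone). The median log2 change was −0.40 (camera adjusted p = 4.53e-10; adjusted p = 0.00792 with an estimated correlation). Kif2c, a mitotic kinesin, and Mki67, the proliferation marker, were each 1.7-fold lower, the spindle checkpoint kinase gene Bub1b 1.68-fold and the mitotic cyclin gene Ccnb1 1.66-fold. Mki67 stood at 9.79 ± 0.08 untreated and 9.03 ± 0.04 with DAC.

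Of 44 tested p53 target genes, 18 rose and 4 fell (19 and 6 adjusted over the list alone), with a median log2 change of 0.22. Without between-array normalization, 13 rose and 8 fell, with a median of 0.11. The list passed with the preset correlation (camera adjusted p = 0.00428) and did not with an estimated correlation (adjusted p = 0.0730). Gdf15, a stress-induced cytokine, rose 1.95-fold, Cdkn1a, which encodes the cell cycle inhibitor p21, 1.8-fold, and Mdm2, the ubiquitin ligase of p53, 1.57-fold. Tap1, which rose 2.48-fold, is a peptide transporter that the antigen presentation list also holds.

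The transcripts of the drug's own targets moved little. Dnmt1, the maintenance methyltransferase, stood at 8.27 ± 0.17 untreated and 8.24 ± 0.07 with DAC (adjusted p = 0.857), and its cofactor Uhrf1 at 9.25 ± 0.17 and 9.19 ± 0.07 (adjusted p = 0.752). The de novo methyltransferase gene Dnmt3b fell 1.31-fold (adjusted p = 0.00737), and the probes of Dnmt3a were detected on no array. Of 27 tested genes of the DNA methylation machinery, 4 rose and 11 fell (4 and 12 adjusted over the list alone), with a median log2 change of −0.21, or −0.135 with 1 member at its bound. The 5-methylcytosine oxidase gene Tet1 was at least 1.05-fold lower, the glycosylase gene Tdg 1.4-fold and Trim28 1.39-fold, while Gadd45g rose 1.39-fold. The list passed narrowly with the preset correlation (camera adjusted p = 0.0481) and not with an estimated one (adjusted p = 0.126), and its call held under 6 of 18 other settings (adjusted p from 0.0167 to 0.112).

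Of 22 tested imprinted genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone). The noncoding RNA gene H19 was 2.52-fold lower, from 7.88 ± 0.08 to 6.54 ± 0.11, and Nnat was 2.57-fold and Ddc 1.71-fold lower. Ppp1r9a, detected on 2 of 3 DAC arrays, had a fitted log2 change of −1.02 (−1.16 to −0.60 over the alternatives). The median log2 change was −0.05, or −0.02 with Mest at its bound. The call (camera adjusted p = 0.0481) was lost with an estimated correlation (adjusted p = 0.167) and held under 5 of 18 other settings (adjusted p from 0.022 to 0.174). The median lay above 0 without untreated replicate 2 (0.03) and with only probes detected on all arrays (0.01).

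**Figure D2:**
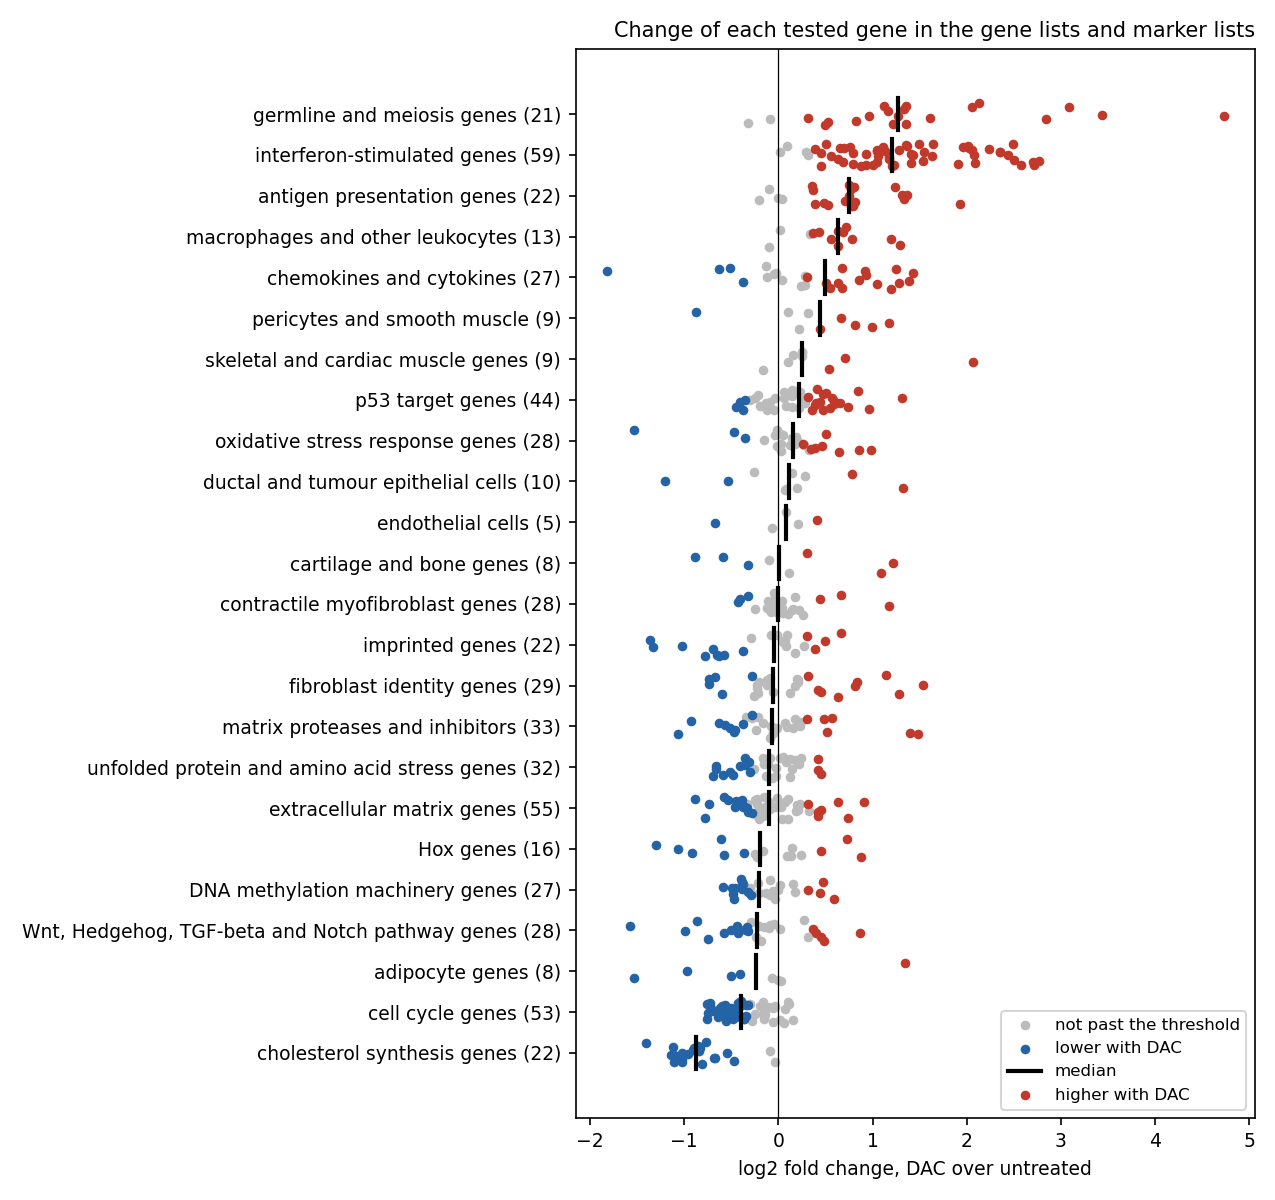
Log2 fold change (DAC over untreated) of each tested gene in the 24 tested lists, with the number of tested genes in brackets. Points are genes, red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise, and black bars are medians. The lists run from cholesterol synthesis genes (median −0.88) to germline and meiosis genes (median 1.27), the latter drawn at fitted values that include genes below detection in one group.

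Genes of the fibroblast and its matrix moved in both directions. In the contractile myofibroblast list, 3 of 28 tested genes rose and 3 fell. Actg2, a smooth muscle actin, rose 2.26-fold and Myh11 1.59-fold, while Tagln (transgelin) was 1.32-fold lower. Lmod1 rose 1.36-fold, a call that ended without between-array normalization (adjusted p = 0.0568, against 0.00133 at the lowest over its alternatives). Of 55 extracellular matrix genes, 7 rose and 13 fell, with Ltbp1 1.87-fold and Col18a1 1.67-fold higher and Col5a2 1.71-fold lower. Col11a1, detected on 2 of 3 DAC arrays, had a fitted log2 change of −0.89 (−1.02 to −0.52 over the alternatives). Of 33 matrix proteases and inhibitors, 6 rose and 9 fell. Mmp10 rose 2.8-fold and Plau, the urokinase gene, 2.64-fold, while Mmp11 was 2.1-fold and Adamts1 1.91-fold lower. Of 29 fibroblast identity genes, 9 rose and 5 fell, with Ly6c1 2.9-fold, Ly6a 2.2-fold and Cspg4 1.76-fold higher. Lrrc15, detected on 2 of 3 untreated arrays, had a fitted log2 change of 1.28 (0.75 to 1.36 over the alternatives). None of these 4 lists passed the test as a whole (camera adjusted p = 0.794, 0.146, 0.555 and 0.498 in this order). Adjusted over the list alone, the counts higher and lower were 3 and 3, 8 and 14, 6 and 9, and 9 and 5. In the contractile list the median change was −0.01 with a mean of 0.05, and in the fibroblast identity list −0.06 with a mean of 0.13. Both medians were above 0 with 75th percentile scaling (0.09 and 0.05).

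Genes of lineage and signalling programmes were also mixed. Of 28 tested genes of the Wnt, Hedgehog, TGF-beta and Notch pathways, 5 rose and 12 fell (7 and 14 adjusted over the list alone), with a median log2 change of −0.22. Beside Bmp4, Smad6 was 1.98-fold and Wnt5a 1.83-fold lower, while Wnt10b, detected on 1 of 3 untreated arrays, rose with a fitted log2 change of 0.87 (0.46 to 0.95 over the alternatives). The list passed with the preset correlation (camera adjusted p = 0.0220) and did not with an estimated one (adjusted p = 0.0963) or without between-array normalization (adjusted p = 0.0694, the highest of a range from 0.00896). Of 16 Hox genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.207). Hoxa4 was 2.46-fold, Hoxa2 2.1-fold and Hoxa5 1.89-fold lower, and Hoxc9 1.84-fold higher. Of 8 adipocyte genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0942). Lpl and Scd1 (1.96-fold) were lower, as was the adipogenic regulator Pparg (1.42-fold), and Plin4 rose 2.53-fold. Of 8 cartilage and bone genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.816), with Sox9 2.12-fold and Col9a3 2.32-fold higher and Sox5 1.5-fold lower.

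Of 9 tested skeletal and cardiac muscle genes, 3 rose and none fell (3 and 0 adjusted over the list alone), with a median log2 change of 0.25. Acta1, the skeletal muscle actin gene, rose 4.2-fold, from 8.30 ± 0.03 to 10.37 ± 0.09, and Myl4 1.63-fold. Mylk2 was at least 1.35-fold higher. The list passed with the preset correlation (camera adjusted p = 0.00656) and not with an estimated one (adjusted p = 0.0871). The myogenic regulators Myod1 and Myog were detected on no array.

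Of 28 oxidative stress response genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone), with a median log2 change of 0.15. The carbonyl reductase gene Cbr3 rose 1.98-fold, the quinone reductase gene Nqo1 1.81-fold, Ftl1 1.56-fold and Gstm1 1.42-fold, while Hmox1 fell. The call (camera adjusted p = 0.0481) was lost with an estimated correlation (adjusted p = 0.126), with cyclic loess (adjusted p = 0.0533) and with array weights (adjusted p = 0.0584). It was also lost with the replicate number as a block and without 5 of the 6 arrays in turn. The camera adjusted p ranged from 0.00323 to 0.0973 over the alternatives. Of 32 genes of the unfolded protein and amino acid stress responses, 3 rose and 11 fell (3 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0888). The serine synthesis genes Phgdh and Psat1 were 1.59-fold and 1.43-fold lower, Cebpb 1.62-fold and Ppp1r15a 1.58-fold.

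Among markers of other cell types that the explant could hold, pericyte and smooth muscle markers were mostly higher beside the leukocyte markers, while epithelial and endothelial markers went both ways. Of 9 pericyte and smooth muscle markers, 5 rose and 1 fell (6 and 1 adjusted over the list alone). Mcam was 1.99-fold higher, beside Actg2, Cspg4 and Myh11, and 5 of the 9 genes are also in the contractile list. Their median log2 change was 0.44 (camera adjusted p = 0.00172; adjusted p = 0.0730 with an estimated correlation). Of 10 ductal and tumour epithelial markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.620). Spint1 and Krt7 were 2.5-fold and 1.72-fold higher, Krt19 and Esrp2 2.3-fold and 1.45-fold lower, and the epithelial genes Epcam and Cdh1 were detected on no array. Of 5 endothelial markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.986), with a median of 0.08 and a mean of −0.01. Esam was 1.59-fold lower, and the rise of Ramp2 (1.33-fold, adjusted p = 0.0452) held under 6 of 18 other settings (adjusted p from 0.00115 to 0.237). The acinar and islet list and the Schwann and nerve list had 2 tested members each, too few for a list test. The proteases Cela1 and Ctrl were 1.42-fold and at least 1.09-fold higher, and Mbp was 1.4-fold lower. The call of Cela1 ended without between-array normalization (adjusted p = 0.0543, against 0.000811 at the lowest over its alternatives). That of Ctrl held under 9 of 14 other settings (adjusted p from 0.0127 to 0.137). It ended without between-array normalization (0.103), without background correction (0.0825), with an offset of 50 (0.137), and without untreated replicate 2 (0.0545) or 3 (0.0771).

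Of the 24 lists tested, 14 passed with the preset correlation. Those for which the call held with an estimated correlation were 5: germline and meiosis, interferon-stimulated, antigen presentation, cholesterol synthesis and cell cycle genes. A call lost in that test does not by itself show that the members vary together. For p53 target genes the call was lost though the estimate, −0.0045, lay below the preset 0.01. For germline genes the estimate was −0.015, and the unadjusted camera p still rose from 2.485e-20 to 0.0005329. By limma's fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, 21 lists passed. Without the filter on dim probes, which brings in members at background, the median log2 changes were 0.78 for interferon-stimulated, 0.35 for antigen presentation and 0.10 for chemokine and leukocyte genes, 0.20 for pericyte markers, 0.04 for muscle, −0.07 for Wnt, Hedgehog, TGF-beta and Notch and −0.09 for DNA methylation machinery genes, and these calls held with the preset correlation. Without between-array normalization, the medians of the muscle and oxidative stress lists were both 0.09, against a median of −0.11 over all genes.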

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

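The list of p53 targets without Tap1 and the counting of probes in place of genes were chosen after seeing the data, and the other alternatives, the further deposited table among them, before. Of 2241 values of 131 named genes under the alternatives, 2220 stayed on their side of the threshold and 21 lost the call, all of Ramp2, Lmod1, Ctrl, Cela1 and Hmox1. No called change turned its sign, while the uncalled changes of Dnmt1 (−0.18 to 0.03) and Uhrf1 (−0.16 to 0.04) turned theirs in 4 values without 1 array. Slide was not run as a block, since no slide was named in the sources used here. Causes were not tested unless given. Genes at least 2-fold lower numbered 64 without background correction, 49 with an offset of 50 and 171 without between-array normalization, and genes at least 2-fold higher 128 with an offset of 50, which shrinks differences of dim probes by construction. Without between-array normalization, 977 genes were higher and 2711 lower. In the further deposited table, 1066 probes were higher and 979 lower, against 1902 and 1992 in the first. Both counts cover all probes, without the detection filter. Genes detected only with DAC numbered 156 and genes detected only without it 166 at a detection p of 0.05, and 25 and 0 at 0.001 against 0.1, where fewer probes qualify. The imprinted median, main value −0.047, lost its call at −0.040 without background correction, −0.037 with an offset of 50, −0.098 with 75th percentile scaling, −0.199 without between-array normalization, −0.009 without a filter, 0.014 with probes detected on all arrays, −0.008 with a detection p of 0.05 and −0.031 with array weights. The DNA methylation machinery median lost it at −0.194, −0.187, −0.205 and −0.306 under the first 4 of these, at −0.135 with probes detected on all arrays and at −0.239 with array weights. The oxidative stress median lost it at 0.164 with cyclic loess and 0.118 with array weights, and the Wnt, Hedgehog, TGF-beta and Notch median at −0.295 without between-array normalization. Lists that gained a call were the unfolded protein list without a filter (median −0.09, adjusted p = 0.0167) and with the mean of probes (−0.126, adjusted p = 0.0386), and Hox genes with probes detected on all arrays (−0.307, adjusted p = 0.0473). The p53 list without Tap1 had a median of 0.21 (adjusted p = 0.00879). Without 1 array in turn, genes higher ranged from 1227 to 1515, genes lower from 1300 to 1613 and lists called from 11 to 13. The imprinted median then ranged from −0.107 to 0.029 and the DNA methylation machinery median from −0.214 to −0.140. The oxidative stress median ranged from 0.111 to 0.192. Genes detected only with DAC ranged from 64 to 86 and genes detected only without it from 42 to 80. The latter count was 80 and 62 without untreated and DAC replicate 1. Leaving out an array can raise these detected-only counts but not lower them, since fewer arrays must meet the thresholds. With the replicate number as a block, 3983 genes were called (3394 without it) and 11 lists, with the imprinted median −0.047, the DNA methylation machinery median −0.207 and the oxidative stress median 0.151 no longer past the threshold, and no other list or named gene changed its call. Deviations of same-numbered plates correlated at 0.317, 0.279 and −0.033 for replicates 1, 2 and 3. Replicates 1 and 2 each matched best with their own number, while untreated replicate 3 correlated best with DAC replicate 2 (0.152). Whether the numbers mark pairs is thus not settled, and the main test left them out as planned. Signal near background limits the folds of dim probes to bounds.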

Other observations

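The groups of fatty acid, checkpoint, S phase and histone genes, and the tests of leukocyte markers, of scaling, of S phase and of histone classes, were chosen after the results were seen, while the splits of the arrays and the intensity-matched lists were planned before. Camera p-values of these gene groups were adjusted over these groups alone. Because the groups were picked from the same arrays, their p-values describe them and are no independent support.

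Fatty acid genes fell beside the cholesterol genes. Of 15 tested genes of fatty acid synthesis, elongation and desaturation, 12 were lower with DAC and 0 higher, with a median log2 change of −0.42 (limma camera adjusted p = 1.51e-06; adjusted p = 0.0607 with an estimated correlation). The desaturase genes Fads2, Scd1, Scd2 and Fads1 fell by 1.51, 0.97, 0.82 and 0.82 on the log2 scale, the elongase gene Elovl6 by a log2 change of −1.12, and Srebf1, the lipid regulator, had −0.42. Of these 15 genes, 1 is in the adipocyte list. Among 9 immune checkpoint and costimulatory genes, 4 rose and 2 fell, with a median of 0.27 (adjusted p = 0.0335; adjusted p = 0.122 with an estimated correlation). Havcr2 and Cd274, which encodes PD-L1, were 3.18-fold and 3.03-fold higher, Cd80 was at least 3.01-fold higher, and Cd47 and Nectin2 had log2 changes of −0.52 and −0.47. Without scaling, the checkpoint median was 0.14, with 4 genes higher and 3 lower, and the direction of both medians was the same under quantile, 75th percentile, cyclic loess and no scaling.

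A target named IAP, a synonym shared by Akp3, Cd47 and Magt1, was 8.07-fold higher with DAC (log2 3.01), while the detected Cd47 probes had log2 changes of −0.52, 0.04 and −0.55 and no probe of Akp3 or Magt1 was detected. The transcript that the IAP probe reads is therefore not known and may belong to none of these genes. Of 33 probes of 18 interferon genes, 3 were detected on all 6 arrays, with log2 changes of 0.14 to 0.29. Most of the others, the probe of Ifnb1 among them, were detected on no array. Limma called 0 of the 33, adjusted over all probes without the detection filter, with 4 at an unadjusted p under 0.05. For probes at background this does not show that the interferon genes were unchanged.

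The rise of interferon-stimulated genes is unlikely to come from scaling, since the list's median log2 change was at least 1.066 under quantile, 75th percentile, cyclic loess and no scaling. Leukocytes among the DAC plates stay open as another explanation. Of 33 leukocyte markers with a probe, 10 of 13 tested were higher and 20 were detected on no array, and their median rise in intensity was 1.5 over all 33 and 13.3 over the 13 tested, with a highest of 264.2, against 258.7 for the 59 interferon-stimulated genes. A probe at background does not show absence and fibroblasts may express some markers themselves, so these values do not decide. An effect of DAC on the fibroblasts stays open too.

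The falls of cell cycle and cholesterol genes could come from scaling or from a trend of the change with intensity. Their medians were −0.392 and −0.864 or lower under the same 4 scalings. Of 10000 random lists matched on intensity, the lowest medians were −0.207 and −0.319, against −0.40 and −0.88 observed. Both tests argue against these explanations, and no biological explanation was tested.

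Replication-dependent histone genes rose unevenly. Of 41 tested, 28 were higher and 7 lower, with a median of 0.56 (adjusted p = 1.51e-06; adjusted p = 0.173 with an estimated correlation). A larger share of cells in S phase is a candidate explanation. However, 22 DNA replication genes had a median of −0.161, with 0 higher and 7 lower. All 22 are in the cell cycle list, in which none was higher, so the 0 was known before these genes were grouped. Their bootstrap 95% interval (−0.323 to −0.047) resampled genes as if independent, so it does not measure the spread between plates. Over the scalings, their median ran from −0.333 (none) to −0.149 (cyclic loess). A single risen copy read by probes of its near-identical copies is argued against by 3 classes with medians above 0.2, H2B (0.57), H3 (0.41) and H4 (0.78), while H2A had −0.28 and H1 0.12. Sharing of signal within a class stays open, and no biological explanation beyond S phase was tested.

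The 6 arrays can be split into 3 and 3 in 10 ways, so no share under 0.1 can be had, and for each result 1 of the 10 splits, the real one, gave a value as large. The real values were 1708 higher, 1686 lower, 231 at least 2-fold higher and 99 at least 2-fold lower genes, and the highest of the other 9 splits was 0 for each, with up to 713 genes at an unadjusted p under 0.05 by limma. For the lists, the real split called 14 and the others 2 to 9 with the preset correlation. With an estimated correlation it called 5 and the highest of the others 0. Each of the other splits held DAC and untreated arrays in both groups, so the DAC difference widened the spread within groups. Low gene counts there are thus built in, and the lists called there may carry part of that difference. These splits therefore do not measure how many calls chance alone would give.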
